A study of Mus musculus with 2 samples.

How the data were processed

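H3K9ac was measured by chromatin immunoprecipitation and sequencing in 2 libraries of mouse kidney at embryonic day 14.5, each from organs pooled from male and female embryos, with a library size range of 300 to 500 bp, per the labels. The libraries are labelled as biological replicates 1 and 2 of 1 group, so no groups were compared. The authors deposited 4 peak lists on mm10, called on replicate 1, on replicate 2 and on both together, and a replicated list derived from the other 3, per the text files deposited with the samples. Every peak of the replicated list is identical to a peak of the list called on both replicates. The unit of the deposited peak height is not stated and was taken as an enrichment ratio on a linear scale from the peak format and the values, which all lie above 1. The deposited significance of each peak is given as a -log10 p-value and a -log10 q-value, and the deposited summit as an offset in bases from the peak start. The labels name a control experiment as a possible control. The caller, the aligner, their versions and the thresholds are not stated, and neither is the read depth.

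The rule behind the replicated list is not stated. On the chromosomes, 24837 of its 30854 peaks (80.5%) overlapped a peak of both replicates by at least 50% of the shorter peak, while 0 of the other 18780 peaks of the list called on both did. Of the rest, 5122 had such a partner in replicate 2 alone, 856 in replicate 1 alone and 39 in neither.

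Peaks on chromosomes 1 to 19, X and Y were kept, and those on unplaced scaffolds were left out of all comparisons (5 in the replicated list). No peak end lay beyond the length of its chromosome in GRCm38.p6. Genes were the 21853 protein-coding genes of GENCODE release M21, with 54361 distinct TSSs. Promoters were windows of 1000 bp either side of each TSS. A promoter peak was any peak that overlapped such a window, so its summit could lie outside it. A promoter was CpG-rich if any window of 500 bp in it had an observed to expected CpG ratio of at least 0.75 and a GC content of at least 0.55, CpG-poor if none had a ratio of at least 0.48, and intermediate otherwise. The class of a peak was that of its midpoint, in the order promoter, exon, intron, intergenic. Domains joined replicated peaks across gaps of up to 1000 bp, and a gene's breadth was that of the widest domain touching its promoter. Distal peaks lay more than 2500 bp from every protein-coding TSS and were assigned to the nearest one.

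Replicate overlap needed 1 shared base and was set beside 20 shuffles of a list within chromosomes. The 24 gene lists covered kidney cell types, cells of other tissues, Hox paralog groups and broadly expressed complexes. Promoter peaks were compared by a two-sided Fisher's exact test of list genes against all other genes, and domain breadth by a two-sided permutation test of the mean percentile with 100000 resamples, in lists with at least 5 marked genes. Distal peaks per gene were compared by a like test with random genes drawn within deciles of the length of genome nearest to the gene. For 25 consensus motifs, the number of distal peaks with a match in the 300 bp at the summit was divided by that in windows 3000 bp to either side, and the ratio ranked among 100 shuffled versions of the consensus, fewer where too few occurred. All p-values were adjusted by Benjamini and Hochberg's method within each family of tests, at 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.

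The lists, tests, thresholds, motifs and most alternatives were chosen before the data were examined. The named genes followed a rule of the same date: the 10 genes with the widest domain, with the highest promoter peak and with the most distal peaks, up to 4 genes of each list with the highest promoter peak, up to 4 without one in alphabetical order, and every Hox gene. Genes named outside this rule are given as such. Intervals of shares are 95% Wilson intervals unless called exact.

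The alternatives were q of 1e-05 or less, heights of at least 4, the list called on both replicates, replicate 1 peaks shared with replicate 2, each replicate alone, promoter windows of 500 and 2500 bp, the most upstream TSS of each gene, other overlap and list length rules, domain gaps of 0 and 3000 bp, distal limits of 1000 and 10000 bp, peaks within 100000 bp of a TSS, other motif windows, and backgrounds of equal CpG class or without olfactory receptors. In the test within CpG classes an exact conditional test took the place of the Cochran-Mantel-Haenszel approximation. After the data were examined, counting each shared domain once and giving a promoter peak to the gene nearest to its summit were added, as were up to 2000 shuffled versions per motif, the long noncoding RNAs and the 14 gene families of the closing section.

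The tests were tested on simulated data, built from the deposited lists for all but the motif test, which used random sequence. Of random lists, 5.5% passed an unadjusted 0.05 in the breadth test, 4.5% in the distal test, 1.6% in Fisher's test and 2.6% in the test within CpG classes. With 6-fold odds of a peak, Fisher's test passed 60.5% of lists and the test within CpG classes 21.5%, so a list that does not pass the latter is not shown to be equal to other genes. With 6-fold odds of no peak these were 92.5% and 38%. The breadth test passed 77.5% of lists weighted 6-fold to broad domains and the distal test 47% of those weighted to genes with 3 or more distal peaks. When 60.3% of peaks were kept in place, 60.8% were recovered as shared. In 6000 regions of random sequence with equal base frequencies, a planted AP-1 motif ranked first among its shuffled versions. There, 2 motifs that were not planted had a permutation p under 0.05. This simulation lacks the differences in base content between real summits and flanks, so it does not show how the motif test behaves on them. Of 300 nearest TSS assignments checked by brute force, 0 differed.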

Results

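Acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the kidneys of mouse embryos at day 14.5. At this stage the ureteric bud branches into a progenitor-rich cortex and the first nephrons form. The series held 1 group of 2 libraries, labelled as biological replicates, each from kidneys pooled from male and female embryos, so no treatment or stage was compared. The question was therefore which genes and regions of the embryonic kidney carried the mark. The deposited peak lists were called on replicate 1 (89980 peaks), on replicate 2 (59693 peaks) and on both together (49640 peaks). A replicated list of 30859 peaks was drawn from the last of these and was used here unless another is named. Peak height is the deposited enrichment ratio, and all positions are on mm10. Heights come from 1 list each and differ in scale between lists, so a height without a named replicate is that of the replicated list and carries no SD. Replicate 1 gave lower heights than replicate 2 at most of the genes named. Read depth was not given, so it is unknown. The intervals below cover counting error only, and every p-value is over genes, not over replicates.

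The strongest peaks of the replicates coincided, and the weakest mostly did not. In replicate 1, 94.7% of the peaks in the first of 5 equal bins by p-value had a partner in replicate 2, against 14.1% in the last bin. In replicate 2 these shares were 99.8% and 13.6%. At the promoter of Pax2, a regulator of kidney progenitors and ureteric bud, the height was 15.2 in replicate 1 and 28.9 in replicate 2. The podocyte genes Nphs1 (nephrin) and Nphs2 (podocin) had weak promoter peaks in replicate 1, at heights of 3.12 and 3.38, and none in replicate 2. Of all replicate 1 peaks on the chromosomes, 33139 of 89975 (36.8%, 95% Wilson interval 36.5 to 37.1) overlapped a replicate 2 peak, against 2.38 ± 0.0576% (SD of 20 shuffles) after shuffled placement. In the other direction, 26385 of 59687 (44.2%, 95% Wilson interval 43.8 to 44.6) overlapped, against 3.55 ± 0.0668%. The lists differ in stringency, since 38.2% of replicate 1 peaks had a q above 0.05, against 6.98% in replicate 2 and 0.995% in the replicated list. The Jaccard index of covered bases was 0.376, and Spearman's rho of heights was 0.608 across the overlapping pairs of peaks, which are not independent replicates. With peaks of q of 1e-05 or less, which are more numerous in replicate 2 (22981) than in replicate 1 (15517), the shares were 96.6% for replicate 1 and 60.8% for replicate 2. For the 20000 best peaks of each list they were 84.7% and 75.025%, and when 50% of both peaks had to overlap 17.5% and 26.4%.

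**Figure D1:**
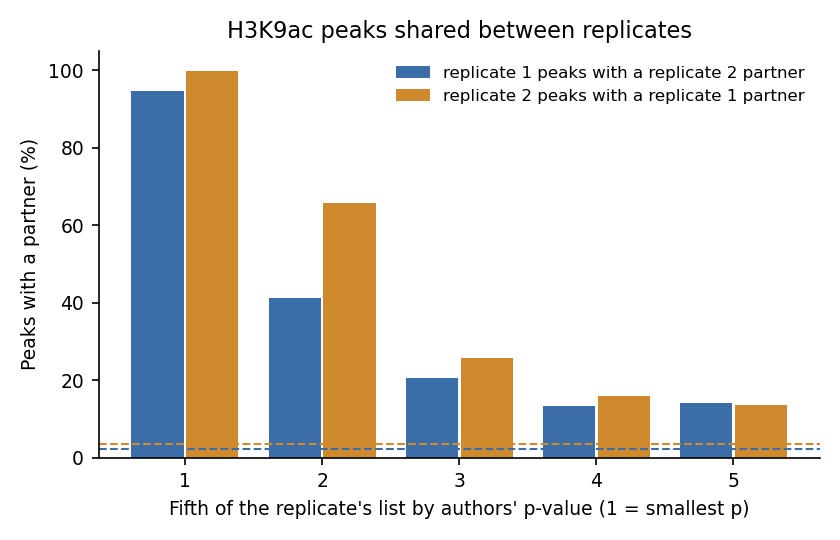
Percentage of each replicate's peaks (vertical axis) that overlapped a peak of the other replicate, in 5 equal bins by the authors' p-value (horizontal axis, 1 holds the smallest p), with blue bars for replicate 1, orange bars for replicate 2 and dashed lines for the mean of shuffled placements. The share fell from 94.7% to 14.1% in replicate 1 and from 99.8% to 13.6% in replicate 2.

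Promoters held most of the replicated peaks, and their peaks were broader and higher than those elsewhere. The 10 genes with the highest promoter peaks ranged from 54.9 to 66.5 in height. Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, had a height of 66.5 (replicate 1, 41.5 and replicate 2, 66.02) at chromosome 4, 133750208 to 133757779. Actb (beta-actin) reached 57.0, Sfpq, a splicing factor, 56.8, Rps6, a protein of the small ribosomal subunit, 55.6 and Ywhaz, a 14-3-3 protein, 54.9. The other genes of the 10 were Bicral (58.9), Irf2bp2 (56.8), Ptma (55.6), Gtf2a1 (55.4) and Csnk1d (54.9). Of replicated peaks on the chromosomes, 54.8% had their midpoint within 1 kb of a protein-coding transcription start site (TSS), a class that makes up 2.37% of the genome (23.1-fold). Introns held 22.5%, intergenic sequence 18.0% and exons 4.76% (2.10-fold). Promoter peaks had a median width of 1076 bp and a median height of 11.4, against 413 bp and 4.26 for intergenic peaks. Single-replicate lists, which hold more weak peaks, put 25.3% (replicate 1) and 35.1% (replicate 2) of their peaks at promoters, 30.2 ± 6.88% (SD, n = 2). Introns, below their share of the genome in the replicated list (0.658-fold), were above it in both single lists, at 1.12-fold and 1.06-fold.

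A promoter peak was present at 13840 of 21853 protein-coding genes (63.3%, 95% Wilson interval 62.7 to 64.0). CpG-rich promoters carried one in 96.2% of cases (11065 of 11503) and CpG-poor promoters in 6.53% (399 of 6107). Hnf1a, a regulator of proximal tubule genes with a CpG-poor promoter, was among the latter, with a height of 9.50. Single lists gave 65.8% (replicate 1) and 65.9% (replicate 2) of genes.

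Genes of nephron progenitors and of the renal stroma were marked almost throughout. All 15 nephron progenitor genes had a promoter peak, among them Wt1, the Wilms tumour gene (height 32.4), Sall1, a zinc-finger factor of the metanephric mesenchyme (29.7), Pax2 (28.3, chromosome 19, 44756631 to 44762996) and Uncx, a homeobox gene of the nephrogenic mesenchyme (23.6). So did 19 of 20 stromal genes, including Pbx1 (35.1) and Meis1 (26.3), a pair of homeobox partners, and Tcf21 (32.2), a stromal and podocyte regulator. Ren1 (renin), made by juxtaglomerular cells, had none. The peaks of Sall1 and Uncx reached the promoter window, but their summits lay 2139 bp and 3745 bp from the gene's nearest TSS. All 19 genes of the early nephron, from renal vesicle to S-shaped body, had a peak, with the Notch ligand Jag1 at 18.9, Pax8 at 18.0 and Ccnd1 (cyclin D1) at 21.6. By Fisher's exact test against all other genes, of which 63.3% had a peak, two-sided and adjusted over 24 lists, the adjusted p was 0.00381 for progenitors, 0.000595 for the early nephron and 0.00381 for the stroma. Within classes of promoter CpG content only the stroma stayed above (19 genes against 14.9 expected, exact adjusted p = 0.00813), while progenitors (15 against 12.4, adjusted p = 0.119) and the early nephron (adjusted p = 0.777) did not pass.

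Among ureteric bud and collecting duct genes, 15 of 17 had a promoter peak, including Spry1, a Ret signalling antagonist (34.3), Etv5, a target of that pathway (19.9) and Wnt11, a ligand of the bud tips (13.8), but not Aqp2, the water channel of principal cells. Podocyte genes had 12 of 14, with Foxc1 at 37.1 and Vegfa at 32.9, and endothelial genes 13 of 15, with Egfl7 at 16.8 and the VEGF receptor Kdr at 8.59. These 3 lists did not pass the test (exact adjusted p = 0.0553, 0.119 and 0.0823). Within CpG classes they did not pass either, with 15 marked ureteric bud genes against 14.3 expected (exact adjusted p = 0.836), 13 endothelial genes against 9.73 (adjusted p = 0.0546) and podocyte genes on the other side, at 12 against 12.2 (odds ratio 0.731, adjusted p = 1). Each list passed under some other settings. The ureteric bud list did so with q of 1e-05 or less (exact adjusted p = 0.0296), heights of at least 4 (0.033), the list called on both replicates (0.0161), the most upstream TSS (0.0308) and peaks given to the gene nearest to the summit (0.0366). Podocyte genes passed on the list called on both replicates (exact adjusted p = 0.00844) and in replicate 1 alone (0.0111), and endothelial genes on the former (0.0356) and in replicate 2 alone (0.0431). Loop of Henle and distal tubule genes had 8 of 17, with Tfap2b at 9.50 and no peak at Kcnj1 (ROMK) (exact adjusted p = 0.217). Proximal tubule genes were below other genes, with 6 of 20 (exact adjusted p = 0.00717). The endocytic receptor Lrp2 (megalin) had 9.27 and its partner Cubn none. This call did not pass in replicate 1 alone (exact adjusted p = 0.211), in replicate 2 alone (adjusted p = 0.0831) or within CpG classes (adjusted p = 0.842).

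**Figure D2:**
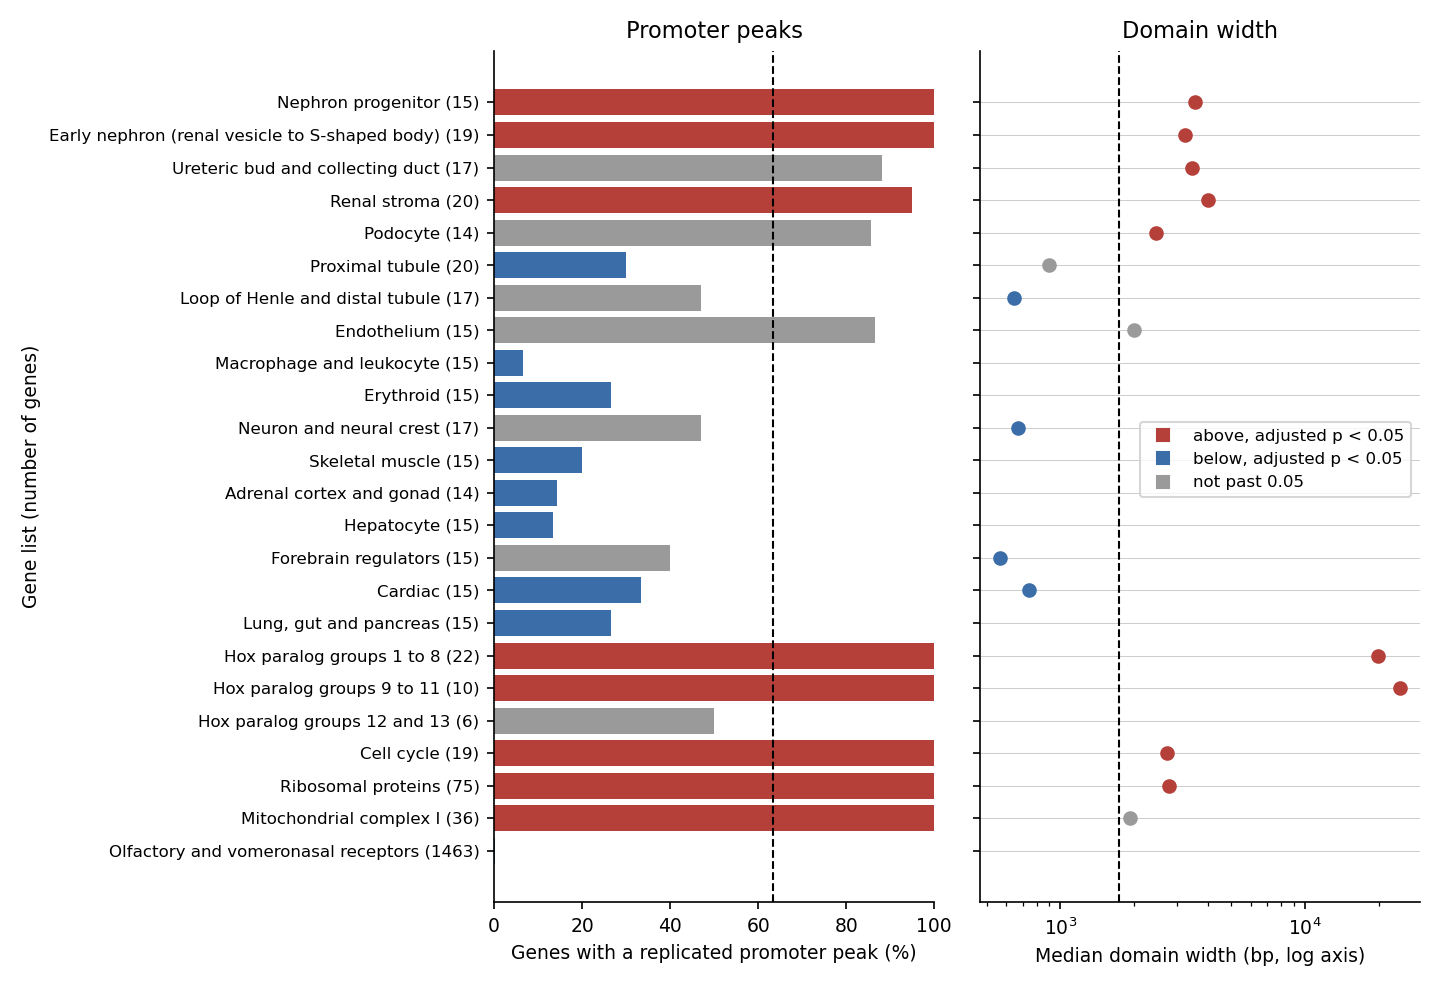
Left, percentage of each of the 24 gene lists with a replicated promoter peak (bars; the dashed line is the share of all genes, 63.3%). Right, median domain width (points, bp on a log axis; the dashed line is the median of all genes with a peak, 1741 bp) of the 16 lists tested, with red for lists above other genes, blue for lists below and grey for lists not past an adjusted p of 0.05.

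Genes of the cell cycle, the ribosome and mitochondrial complex I were marked in full in the replicated list. All 19 cell cycle genes (Cdk1 29.4, Mki67 29.0 and Ccnb1 26.4), all 75 ribosomal protein genes and all 36 genes of mitochondrial complex I had a promoter peak (exact adjusted p = 0.000595, 1.87e-14 and 6.61e-07). Within CpG classes none of these lists passed (exact adjusted p = 1, 0.112 and 0.227). With peaks given to the gene nearest to the summit, 77.8% of complex I genes kept one (exact adjusted p = 0.0412), against 98.7% of ribosomal protein genes and all cell cycle genes.

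Genes of other tissues were mostly unmarked. Of 15 macrophage and leukocyte genes only Coro1a had a peak, at a height of 3.12, and Adgre1 (F4/80) and C1qa had none. Hepatocyte genes had 2 of 15, with Apoh at 16.2 and none at Alb (albumin) or Afp. Adrenal and gonadal genes had 2 of 14, and 1 of these, Inha, had its summit nearer to the TSS of Obsl1. Skeletal muscle genes had 3 of 15, of which Mylpf and Actn3 had summits nearer to the TSS of Tbc1d10b and of Zdhhc24. Erythroid genes had 4 of 15, with Klf1, the erythroid Kruppel-like factor, at 13.2 and none at Gata1. Cardiac genes had 5 of 15 (Ryr2 at 5.95, Hand1 at 4.79 but with no peak in replicate 1, and none at Myh6, which had one of 2.71 in replicate 1), and lung, gut and pancreas genes 4 of 15 (Foxa1 at 4.64, and Foxa3 with a summit nearer to the TSS of Sympk). All 7 lists were below other genes (exact adjusted p = 4.67e-05, 0.000394, 0.000626, 0.00187, 0.00858, 0.0395 and 0.00858, in this order), as were olfactory and vomeronasal receptors with 2 of 1463 genes (odds ratio 0.000648). Some of these calls did not hold in each peak list. In replicate 1 alone muscle (exact adjusted p = 0.473) and adrenal and gonad (adjusted p = 0.135) did not pass, in replicate 2 alone cardiac (adjusted p = 0.204) and lung, gut and pancreas (adjusted p = 0.0786) did not. The last 2 lists also did not pass on the list called on both replicates (exact adjusted p = 0.474 and 0.217), nor did cardiac genes with peaks given to the nearest gene (0.0734). The peak of Coro1a was lost with q of 1e-05 or less and with heights of at least 4.

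A partly different set passed as below other genes once promoters of equal CpG class were compared. Forebrain regulators had 6 marked genes against 14.4 expected (exact adjusted p = 7.6e-09), with Emx1 at 7.19, Dlx1 at 5.56 and none at Foxg1. Neuronal and neural crest genes had 8 against 11.7 (exact adjusted p = 0.0373), with Elavl4 at 14.8, the proneural factor Ascl1 at 6.72 and Mpz with a summit nearer to the TSS of Sdhc. Lung, gut and pancreas (4 against 8.65, exact adjusted p = 0.000339), adrenal and gonad (2 against 6.08, adjusted p = 0.00871) and olfactory receptors (2 against 157, adjusted p = 6.18e-86) were below as well. Muscle (exact adjusted p = 0.191), erythroid (0.836), macrophage (0.601), hepatocyte (0.158) and cardiac (0.233) lists did not pass. Their odds ratios were 0.193, 0.56, 0.231, 0.144 and 0.406, in this order, against 0.232 for the neuronal list. The test passed only 38% of simulated lists with 6-fold odds of no peak. Not passing it therefore does not show that CpG class accounts for these lists. Without regard to CpG class the neuronal (8 of 17, exact adjusted p = 0.217) and forebrain (6 of 15, adjusted p = 0.119) lists did not pass. The neuronal list did pass with q of 1e-05 or less (exact adjusted p = 0.0157) and for replicate 1 peaks shared with replicate 2 (0.00341), and the forebrain list for the latter (0.0415), with the most upstream TSS (0.0455) and without olfactory receptors in the background (0.039), all below other genes. Against all other genes, other peak lists turned the direction without passing. In replicate 2 alone 12 of 17 neuronal genes had a peak (70.6%, exact adjusted p = 0.802), and on the list called on both replicates 66.7% of forebrain genes did (adjusted p = 1), both above other genes. All 15 forebrain genes have CpG-rich promoters, of which 97.1% carried a peak on the latter list, so the direction within CpG classes did not turn there. The test within CpG classes was run on the replicated list only.

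The 3 broadest acetylated promoter domains lay in the Hox clusters, which set position along the body axis. A promoter peak was present at 36 of 39 Hox genes. The widest domain ran over 58537 bp from Hoxb8 to Hoxb3 (chromosome 11, 96276328 to 96334864), the next over 50174 bp from Hoxa5 to Hoxa11 (chromosome 6, 52199862 to 52250035), and others over 26058 bp at Hoxc9 and Hoxc10 and 22705 bp from Hoxd9 to Hoxd11. The Hoxa domain met Hoxa3 only in the upstream part of its long annotation and left out Hoxa4. Not all Hox genes of groups 1 to 11 had broad domains, with 821 bp at Hoxd1, 970 bp at Hoxb1, 2195 bp at Hoxc4 and 2621 bp at Hoxa4. These widths depended on the library. In replicate 1 the widest domain within Hoxa5 to Hoxa11 had 26324 bp, at Hoxa7, Hoxa9 and Hoxa10, and that within Hoxd9 to Hoxd11 7830 bp. In replicate 2 these were 50211 bp, from Hoxa5 to Hoxa11, and 38861 bp, the latter in a domain that also reached a promoter of Hoxd3. The Hoxb3 to Hoxb8 domain had 50159 bp in replicate 1 and 79111 bp in replicate 2, where it also took in Hoxb2. The Hoxc9 and Hoxc10 domain had 25867 bp and 29716 bp. Heights were lower at the posterior end of the Hoxa and Hoxd clusters. Hoxd11, which acts with its group 11 paralogs in kidney induction, reached 39.4, Hoxd12 8.06 and Hoxd13 5.67. Hoxa11 reached 22.4 and Hoxa13 4.17. Toward the anterior end heights were mixed. Hoxd1 had 8.11, Hoxd4 7.77 and Hoxd3, annotated over the same stretch as Hoxd4, 23.3. Hoxa1 had 12.4 and Hoxa2 13.2, and Hoxb1 had 2.48 but its neighbour Hoxb2 45.7, the highest of all Hox genes in the replicated list. The summit of this Hoxb2 peak lay 1676 bp from the gene's TSS, and the peak also lay at the promoter of the long noncoding RNA Hoxb3os. In replicate 1 Hoxb2 had 18.0, below Hoxb6 at 26.2. Hoxb13 and Hoxc12 had no peak in any list, and Hoxc13 had one in replicate 1 alone (4.46) and on the list called on both replicates. All 22 genes of groups 1 to 8 (exact adjusted p = 0.000297) and all 10 of groups 9 to 11 (adjusted p = 0.0256) had a promoter peak, against 3 of 6 in groups 12 and 13 (adjusted p = 0.676), and Hoxb7 was counted with the ureteric bud. The peak of Hoxb1 was absent from replicate 1 and was lost with q of 1e-05 or less and with heights of at least 4, which left 95.5% of groups 1 to 8 marked in each case, and that of Hoxa13 was lost at the same q. Within CpG classes neither of the first 2 sets passed (exact adjusted p = 0.199 and 1), and groups 1 to 8 did not pass with peaks given to the nearest gene (81.8%, adjusted p = 0.0638).

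**Figure D3:**
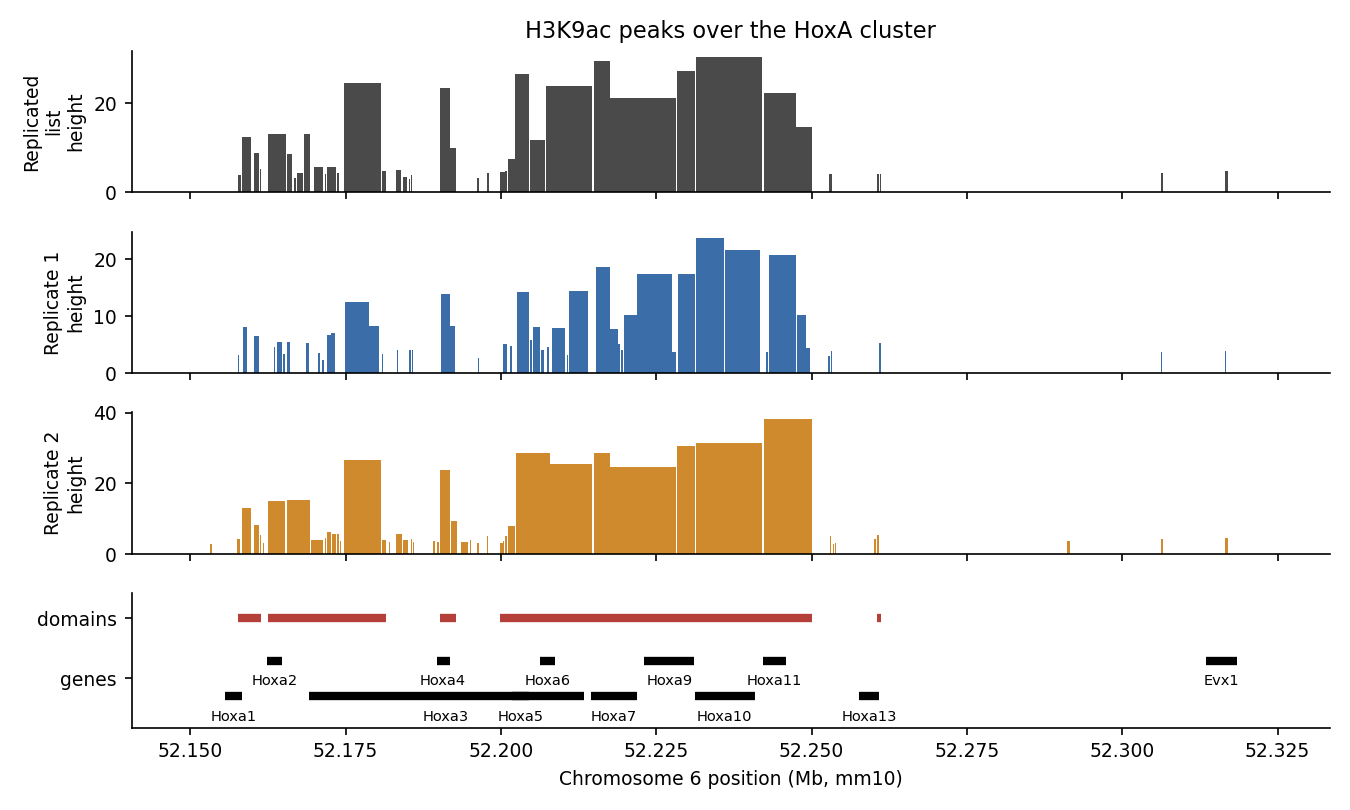
Peaks across the Hoxa cluster (horizontal axis, chromosome 6, mm10, Mb), with bars as wide as each peak and as high as its enrichment ratio (vertical axes, 1 scale per list) in the replicated, replicate 1 and replicate 2 lists, domains in red and genes in black. Peaks reached 30.2 in the replicated list at Hoxa10 and 4.17 at Hoxa13.

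Genes of several kidney cell types had broad domains as well. Domain breadth is the length of replicated peaks joined across gaps of up to 1 kb at a promoter. Outside the Hox clusters the broadest lay at Nr2f2 (COUP-TFII), a nuclear receptor (25740 bp, chromosome 7, 70345439 to 70371178), Bahcc1 (21751 bp), Gata3, a ureteric bud regulator (20839 bp, chromosome 2, 9868851 to 9889689) and Meis2 (20673 bp). Pax2 had 16706 bp, Sall1 12711 bp and Wt1 12445 bp, against a median of 1741 bp over all genes with a peak. In replicate 1 Gata3 had 9864 bp and Pax2 8248 bp, against 21945 bp and 18519 bp in replicate 2, while Nr2f2 had 25531 bp and 27743 bp. Median breadth was 24382 bp for Hox groups 9 to 11, 19904 bp for groups 1 to 8, 3998 bp for the stroma, 3546 bp for progenitors, 3456 bp for the ureteric bud, 3216 bp for the early nephron and 2458 bp for podocytes. Ribosomal protein (2778 bp) and cell cycle genes (2734 bp) were broader as well. Lists below other genes past the threshold were forebrain (564.5 bp), loop and distal tubule (645.5 bp), neuronal (670 bp) and cardiac (743 bp) genes. In a two-sided permutation test over 16 lists, adjusted p was 5.33e-05 for both Hox sets and ribosomal proteins, for which the unadjusted p of 1e-05 is the smallest the permutations can give. It was 0.00012 for the stroma, 0.00016 for the early nephron, 0.00032 for the ureteric bud, 0.00054 for the cell cycle, 0.00433 for progenitors and 0.0219 for podocytes, and 0.000267, 0.0111, 0.00267 and 0.00206 for the lists below. Endothelial (2004 bp, permutation adjusted p = 0.351), proximal tubule (896 bp, adjusted p = 0.088) and complex I genes (1926.5 bp, adjusted p = 0.254) did not pass, but proximal tubule genes were below other genes in replicate 1 alone (adjusted p = 0.00859) and in replicate 2 alone (adjusted p = 0.0295).

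Members of a Hox set often shared a domain. Counted once per domain, groups 1 to 8 had 13 domains of median 3768 bp (adjusted p = 0.000192) and groups 9 to 11 had 5 of median 22705 bp (adjusted p = 8e-05, permutation test). Without joining peaks, progenitors (permutation adjusted p = 0.183) and the cell cycle (adjusted p = 0.207) did not pass. Podocytes did not pass in replicate 1 alone (permutation adjusted p = 0.103), on the list called from both replicates together (adjusted p = 0.223) or within CpG classes (adjusted p = 0.0739). The loop and distal tubule list ended within CpG classes (permutation adjusted p = 0.185) and at q of 1e-05 or less (adjusted p = 0.0509), and the neuronal list at that q (adjusted p = 0.0686) and with gaps of 3 kb (adjusted p = 0.186). Cardiac genes, with 3 marked genes at that q, were too few to be tested there.

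Distal peaks clustered around kidney developmental genes. Among peaks assigned to the gene with the nearest TSS, Pax2 had 15, the highest at chromosome 19, 44725885 to 44726604 (intergenic, height 25.7, 29.8 kb from the nearest TSS). Meis1 had 17, Uncx 16 and Sall1 10. Wnt7b, a ureteric Wnt ligand, had 9, with an intergenic peak of height 18.5 at chromosome 15, 85645346 to 85646976, and Wnt11 had 7, the highest at chromosome 7, 98814337 to 98815425 (intergenic, height 17.2). Six2, which maintains nephron progenitors, had 6, the highest at 85690947 to 85693574 on chromosome 17 (intergenic, height 10.6). Wnt7b and Six2 were chosen for naming after their values were seen. Over all genes the most distal peaks lay nearest Gse1 (40), Zmiz1 (34), Zfp36l1 (28) and Smad7 (27), the last an inhibitor of TGF-beta signalling. Distal peaks, more than 2.5 kb from any protein-coding TSS, numbered 10484 (34.0% of replicated peaks), at a median of 18063 bp from the nearest TSS. Some of them were also part of the broad promoter domains above. The highest distal peaks of Uncx and Sall1 lay inside the domain at their promoter, while those of Pax2, Meis1 and Wnt11 lay outside. Domain breadth and distal counts thus share peaks and are not independent.

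Progenitor genes had 4.2 distal peaks per gene against 0.777 for random genes matched for the length of genome nearest to them, stromal genes 3.6 against 0.824, early nephron genes 2.84 against 0.843, ureteric bud genes 2.76 against 0.667 and podocyte genes 2.29 against 0.726. Hox groups 1 to 8 had 1.82 against 0.189 and groups 9 to 11 had 1.1 against 0.136, while olfactory and vomeronasal receptors had 0.0178 against 0.309. The adjusted p over 24 lists (two-sided permutation test) was 0.00198, 0.00198, 0.0138, 0.0072, 0.0344, 0.00012, 0.00298 and 0.00012, in this order, where 0.00012 stands for an unadjusted p of 1e-05, the smallest the permutations can give, and the other 16 lists did not pass. With distal peaks more than 10 kb from a TSS, the early nephron (1.68 per gene, permutation adjusted p = 0.0884), ureteric bud (1.76, adjusted p = 0.0507), podocyte (1.43, adjusted p = 0.124) and both Hox sets (0.364 and 0.3, adjusted p = 0.0706 and 0.0632) did not pass. Podocytes also did not pass with peaks of q of 1e-05 or less (permutation adjusted p = 0.076), with heights of at least 4 (adjusted p = 0.0615) or on the list called from both replicates together (adjusted p = 0.0553).

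**Figure D4:**
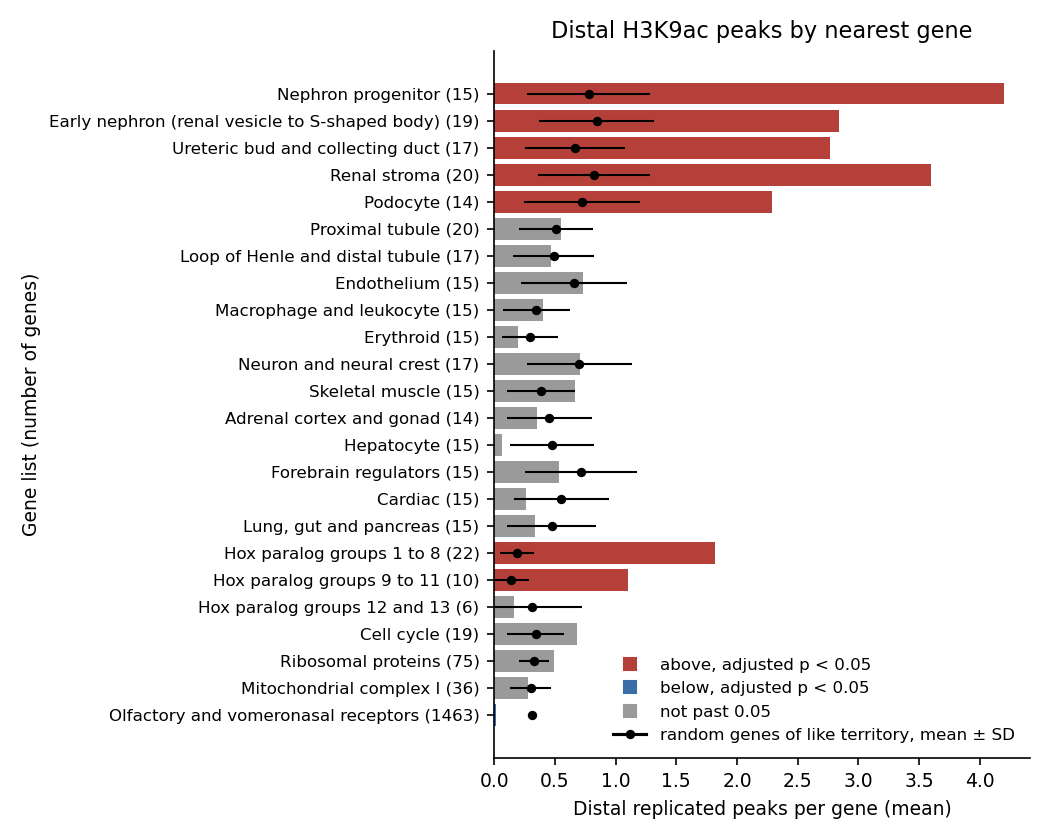
Mean number of distal replicated peaks per gene (bars, horizontal axis) for the 24 gene lists, with black points and lines for the mean and SD of random genes matched for territory length, and red for lists above them, blue below and grey not past an adjusted p of 0.05. Nephron progenitor (4.2 against 0.777) and renal stroma genes (3.6 against 0.824) had the highest means.

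At the summits of distal peaks the posterior HOX consensus TTTTACGA had a higher ratio than any of its 100 shuffled versions, but no motif passed the test after adjustment. It occurred in 19 summit windows against 12 in flanking windows, a ratio of 1.58 against a median of 0.567 for its 100 shuffled versions, all of which lay lower (permutation p = 0.0099, adjusted p = 0.238). Single bases were shuffled, so most versions lost the CG of this consensus, and its rank cannot be told apart from CpG content. Its unadjusted permutation p was under 0.05 in replicate 2 alone but not in replicate 1 alone. MEF2 had 42 against 48 (permutation p = 0.0297, adjusted p = 0.356). PAX2/8 (ratio 0.762) had a permutation p of 0.815. Of 24 motifs, 0 passed an adjusted p of 0.05 and 2 had an unadjusted permutation p under 0.05, but with 100 shuffled versions no single motif can pass, so this count carries no information. With up to 2000 versions per motif, a number chosen after these results were seen, 4 of 839 versions of the posterior HOX consensus reached its ratio (permutation p = 0.00595, adjusted p = 0.143). In that test 0 motifs passed and 3 had an unadjusted permutation p under 0.05, namely posterior HOX, MEF2 and HNF1. Of these, HNF1 matched only 1 summit window against 1 flanking window, and MEF2 matched fewer summit than flanking windows. Motifs with few distinct versions, such as SP/KLF with 8, still could not pass.

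The X chromosome carried fewer and lower peaks than every autosome. It had 4.33 replicated peaks per Mb, against 7.79 (chromosome 14) to 22.8 (chromosome 11) on the autosomes. Among genes with CpG-rich promoters 88.6% on X had a promoter peak, against 90.3% to 98.7% on the autosomes. The median height at these X promoters was 10.9, against 16.7 to 18.8 on the autosomes, and the ratio to the autosome median was 0.616 (0.634 in replicate 1 and 0.601 in replicate 2). X also had fewer CpG-rich promoters, at 31.5% of its genes against 40.3% to 69.3%. No test was run across chromosomes.

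**Figure D5:**
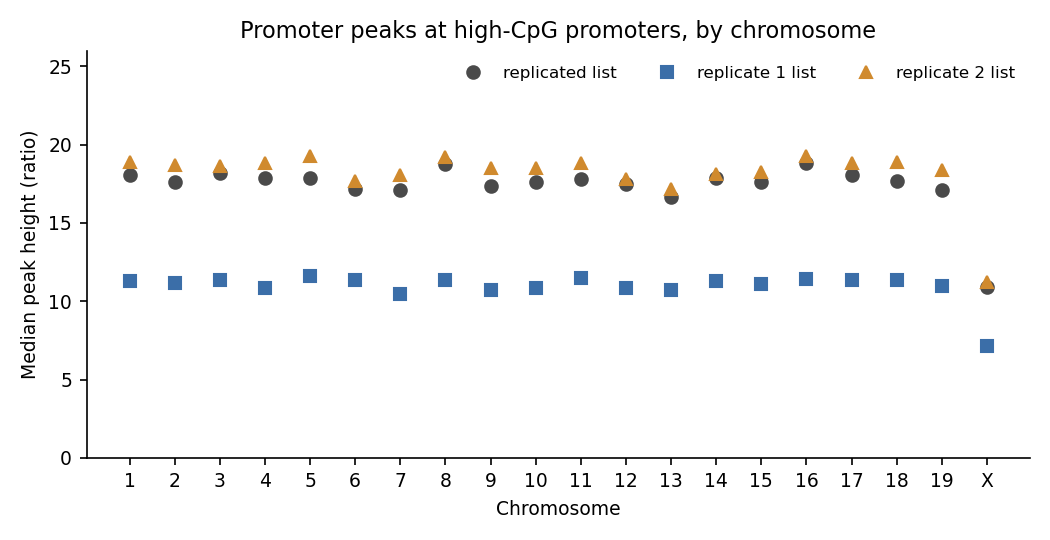
Median height of promoter peaks (enrichment ratio, vertical axis) at genes with CpG-rich promoters on each autosome and X (horizontal axis), with circles for the replicated list, squares for replicate 1 and triangles for replicate 2. In the replicated list X lies at 10.9 and the autosomes between 16.7 and 18.8.

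Genes with a promoter peak in 1 replicate were few and their peaks were low. Replicate 1 alone had a peak at 649 genes (median height 3.38) and replicate 2 alone at 677 (median height 3.63), while 13730 genes had one in both and 6797 in neither. Among them, the neural crest factor Foxd3 (3.12) and the muscle creatine kinase gene Ckm (3.92) had a peak in replicate 1, and the endothelial receptor Tek (4.29) and the neuronal RNA-binding protein gene Elavl3 (4.03) in replicate 2. With q of 1e-05 or less the counts became 49 for replicate 1 and 1671 for replicate 2, and with heights of at least 4 they became 313 and 895. These counts describe 1 library on each side and were not themselves tested. Tests of lists for other tissues among these genes are given in the closing sections.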

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

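The tests of X copy number and of the genes not called in both replicates within CpG classes were chosen after their results were seen.

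The replicated list held 5 peaks on scaffolds outside the assembled chromosomes, sequence that no comparison used. The highest, with a height of 16.7, lay on scaffold 4_GL456216_random, and 3 lay on X_GL456233_random.

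Most peaks of each replicate had no partner in the other. Peaks near the detection limit are a candidate explanation, since 94.7% of the best bin of replicate 1 peaks had a partner in replicate 2 against 14.1% of the last. Tissue of a neighbouring organ in 1 dissection could also add peaks to that library, and 8 of 18 combinations of a list for another tissue and a replicate passed an adjusted p of 0.05 with more genes called in that replicate alone. These 8 included forebrain regulators in replicate 2 (3 of 15, Fisher's exact test, adjusted p = 0.0229). The forebrain is no neighbour of the kidney, so this test cannot tell a dissected neighbour from weak calls. When only genes not called in both replicates were compared within CpG classes 1 combination passed, neuronal and neural crest genes in replicate 2 (6 of 11 against 1.78 expected, exact adjusted p = 0.0446). Stray tissue therefore cannot be told apart from weak calls at genes without a strong peak, and no biological explanation was tested, since the design holds 1 group.

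The X chromosome had fewer peaks per Mb than each autosome. A lower number of CpG-rich promoters could lower peak density. Among such promoters alone 88.6% on X had a peak, a little below the 90.3% of the lowest autosome. Their median height on X was 0.616 of the autosome median. The number of CpG-rich promoters thus does not account for the lower heights. Height does not measure peaks per Mb, so its part in the lower density stays open. The level per promoter was lower too, with an X median height of 10.9 against 16.7 on the lowest autosome, which describes the pattern and gives no cause. Inactivation of 1 X in female cells is a candidate explanation, since 4 genes known to escape it (Kdm5c, Kdm6a, Eif2s3x and Ddx3x) had a median height of 25.8 against an upper quartile of 14.6 on X (one-sided permutation p = 4e-05), but they also stood above the autosome median of 17.8, so their height need not come from escape. Fewer X copies in a pool of both sexes would give a ratio of 0.75 with equal numbers and no other difference, and the measured 0.634 in replicate 1 leaves this open, since the sex ratio of the pools is not given and height need not scale with copies.

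Forebrain regulators carried promoter peaks at 6 of 15 genes in a kidney sample, at Emx1 (7.19), Lhx6 (6.44), Dlx1 (5.56), Dlx2 (4.94), Lhx2 (4.83) and Eomes (4.32), the last a pair outside the rule for named genes. Peaks of neighbouring promoters could explain them, but 0 of the 6 summits lay nearer to the TSS of another gene. Weak calls could as well, and 6 of 6 had q of 1e-05 or less. That cut could hardly fail, since 60.9% of genes kept a promoter peak at it, against 63.3% without it. The median height of the 6 lay at percentile 9.25 of genes with a promoter peak. Neighbouring promoters are thus argued against, while this test cannot decide on weak calls. Cells of another type in the pooled tissue or low acetylation of these CpG-rich promoters in kidney cells stay open and were not tested.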

How the results depend on the processing

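Counting each shared domain once, up to 2000 shuffled versions per motif and giving a peak to the gene nearest to its summit were chosen after the results were seen, and all other alternatives before. Of 2429 results under an alternative, 2155 stayed on the same side of their test or within their spread, 106 moved and 45 turned direction. Most of these results only ask whether 1 of the 169 named genes kept its promoter peak or its lack of one, and many of those genes were picked for high peaks. Some could not change, such as merging overlapping peaks in lists without overlaps. The totals therefore say little about how stable the tests were. List tests newly passed in 18 cases and no longer passed in 40, and a named gene gained a promoter peak in 36 and lost it in 29. No list that turned direction passed its test in the replicated list. The count of motifs that passed, 0 in each setting, carries no information on stability with 100 shuffled versions. Read depth is not given, so its effect on the number of peaks in each list is unknown. Fewer and stronger peaks follow from the stricter q and height by construction, and for the rest the cause was not tested. No paired analysis was possible because the series holds 1 group.

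With q of 1e-05 or less, 96.6% of replicate 1 and 60.8% of replicate 2 peaks were shared, promoters held 69.2% of peaks, 60.9% of genes had a promoter peak, 1 list was below others in breadth (cardiac, with 3 marked genes, was not tested), and 49 and 1671 genes were called in replicate 1 or 2 only. With heights of at least 4 these were 68.8%, 65.4%, 68.3% and 60.9%, with 313 genes in replicate 1 only and 895 in replicate 2 only. Replicate 1 and 2 shares were 34.2% and 40.2% with overlap of 50% of the shorter peak, 17.5% and 26.4% with 50% of both, 48.7% and 39.9% at equal list lengths (390 genes in replicate 1 only and 933 in replicate 2 only) and 84.7% and 75.025% for the top 20000. Promoter share and genes with a peak were 39.6% and 65.5% on the list called on both replicates, 63.7% and 61.4% for shared replicate 1 peaks (2 lists below in breadth, with cardiac at 20% and neuronal at 23.5% marked and not tested), 40.8% and 62.7% with windows of 500 bp, 65.0% and 64.4% with 2.5 kb, and 45.7% and 60.6% with the most upstream TSS. Without either replicate they ranged from 25.3% to 35.1% and from 65.8% to 65.9%, with 7 to 8 lists below in breadth and introns at 1.06-fold to 1.12-fold. Within CpG classes 1 list was above and 5 below at promoters, and beyond 10 kb 2 lists were above in distal peaks.

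Lists that turned direction were these. At promoters, forebrain (66.7%) and Hox groups 12 and 13 (66.7%) did so on the list called on both replicates, and podocyte (85.7%) and loop and distal tubule (47.1%) within CpG classes, and without either replicate neuronal genes ranged from 47.1% to 70.6% and Hox groups 12 and 13 from 50% to 66.7%. In breadth, the mean percentile of endothelial genes was 43.4 at the stricter q, 39.7 with heights of at least 4, 47.8 for shared replicate 1 peaks, 41.1 with gaps of 0 bp and 42.6 with the most upstream TSS. In distal peaks per gene at the stricter q they were neuronal (0.235), adrenal (0.214), forebrain (0.333) and Hox 12 and 13 (0.167), and with heights of at least 4 endothelium (0.267), neuronal (0.294), forebrain (0.4) and Hox 12 and 13 (0.167). On the list called on both replicates they were loop and distal tubule (1.12), macrophage (0.6), neuronal (1.12) and complex I (0.667), and for shared replicate 1 peaks proximal tubule (0.35), endothelium (0.4), neuronal (0.353) and complex I (0.25). Beyond 10 kb they were proximal tubule (0.2), endothelium (0.333), neuronal (0.412), muscle (0.2) and complex I (0.194), beyond 1 kb proximal tubule (0.6) and macrophage (0.4), and within 100 kb loop and distal tubule (0.471) and macrophage (0.133). Without either replicate, ranges were 0.8 to 2.07 for macrophage, 1.24 to 3.53 for neuronal, 1.07 to 1.87 for muscle, 0.933 to 4.33 for cardiac, 1.33 to 3.47 for lung, gut and pancreas and 0.556 to 1.67 for complex I.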

Other observations

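The long noncoding RNAs and gene families of this part were chosen after the other results were seen, and so were their tests.

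Promoters of long noncoding RNAs were seldom marked. Of 7897 such genes more than 2.5 kb from any protein-coding TSS, 738 (9.35%) had a replicated peak at their promoter, with a median height of 5.56. The highest included 1810026B05Rik (63.7), Mir17hg, the host of a microRNA cluster that promotes proliferation (46.1), Dancr (36.9), Malat1, an abundant nuclear RNA (36.5) and the snoRNA host Snhg17 (35.8). Of the 10484 distal peaks, 870 (8.30%) lay at such promoters.

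Families of signalling and structural genes differed in how many members were marked, by a two-sided Fisher's exact test adjusted over 14 families. All 10 Frizzled genes, the Wnt receptors, had a promoter peak (median height 21.6, exact adjusted p = 0.0478), as did 36 of 44 collagens (adjusted p = 0.0401) and 59 of 67 histone genes (adjusted p = 4.48e-05). Cytochromes P450 (21 of 94, exact adjusted p = 1.16e-14) and keratins (9 of 49, adjusted p = 9.58e-10) were below other genes. Wnt ligands (16 of 19, exact adjusted p = 0.161), Iroquois factors (6 of 6, adjusted p = 0.161) and solute carriers (249 of 361, adjusted p = 0.0641) did not pass. The families were not tested within CpG classes, so these differences cannot be told apart from differences in promoter CpG content.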
